A study of Mus musculus with 6 samples.

How the data were processed

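RNA of terminal ileum was measured in 6 libraries, 3 labelled NEC and 3 labelled control, from mice aged 9 days. Per the labels' protocols, total RNA was taken with a column kit, samples with an integrity number above 7 were used, and paired-end libraries were made with the TruSeq RNA kit. Per the submitters' processing notes, HISAT2, SAMtools 1.3.1 and Cuffdiff were used with the mouse build mm10. The version of the other tools, the annotation and the strand setting were not given in the sources used here.

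The deposited table held 1 value per gene and library and named no unit in its header. The values were read as FPKM made by the authors, since Cuffdiff, named in the submitters' processing notes, gives FPKM, and since the low values of single-transcript genes fell on steps of 1 fragment scaled by transcript length. Columns whose names begin with N were read as the NEC libraries of the same number, as no other group has that initial. All columns of values were used. Of the steps below 100 fragments, 78.9% to 94.0% of values per library were whole within 0.01. They gave a depth of 15.2 to 18.7 M fragments per library, an estimate, and whole fragments could be recovered for single-transcript genes only. Total FPKM ranged from 394613 to 628698 per library, and the 7SL RNA gene Rn7s1 held 42.7% of the total in NEC 1 and 27.3% to 32.2% in the others. Of 55487 gene identifiers, 55141 matched GENCODE mouse release M21, on the same build, from which symbols, coordinates and biotypes were taken, and 21904 genes were at 0 in all libraries.

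The comparison used limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), over genes with a mean of at least 1 FPKM in the 6 libraries. Group was the only term. Calls had a Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates the change of genes of low value. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so no such test was used.

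The 38 gene lists, the test and the rule for naming genes were fixed before the data were examined. The rule takes the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, without predicted genes and pseudogenes. It also takes up to 4 members per list with the smallest p or called against the list, and Becn1, Map1lc3b, Sqstm1, Atg5, Atg7, Ulk1, Tlr4, Lgr5 and Muc2. The 31 lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Autophagy and lysosome lists were also compared with all other tested genes by two-sided Fisher's exact tests.

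Alternatives covered pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, TMM scaling, quantile normalization, the replicate number as a block, no trend, sample weights, and each library left out in turn. TMM factors were computed without weights, trimming 30% of log ratios and 5% of mean levels at each end. Settings chosen after seeing the data were a scaling to protein-coding genes outside the 100 most abundant, protein-coding genes only, and leaving out genes on X and Y. The gene test was tested on simulated data with the levels of the 15806 genes of the NEC and control comparison, of which 200 were changed. It recovered 87% of changes of log2 1 and 97% of changes of log2 2, and 10 calls, 5.15%, were false. The simulation drew independent noise of the same spread for both groups. The real libraries had a median within-group SD of 0.21 in NEC and 0.09 in control, and 6044 genes were called. The simulated shares therefore may not carry over to these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.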

Results

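The series profiled RNA of the terminal ileum, the last part of the small intestine, of C57BL/6 mice on postnatal day 9, in 3 libraries labelled NEC and 3 labelled control. NEC stands for necrotizing enterocolitis, an inflammatory bowel disease of preterm infants, and the series title gives autophagy-related genes in it as the subject. In mice it was induced by gavage of hyperosmolar formula, hypoxia at 5% O2 for 10 min 3 times per day over 4 days, and oral lipopolysaccharide at 4 mg/kg per day on postnatal days 6 and 7. The same treatment text stands on the control labels, so the feeding and handling of the controls is not stated. The deposited values carry no stated unit and were read as FPKM, fragments scaled to transcript length and to the mapped fragments of the library. Their smallest steps correspond to 16.9, 18.2 and 18.7 M fragments in NEC 1, 2 and 3, and to 15.6, 15.2 and 16.2 M in control 1, 2 and 3. Genes at 1 FPKM or more numbered 13461, 14541 and 14882 in the NEC libraries and 16585, 16702 and 16290 in the controls. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical. Sex-linked genes set NEC 1 apart from NEC 2 and 3, so the NEC libraries did not all come from the same material.

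The first question was which genes differed between NEC and control ileum. The largest rises in NEC included genes of fat and sugar absorption and of glutathione conjugation. Fabp1, a fatty acid-binding protein of absorptive cells (chromosome 6, 71199827 to 71205023), was at 137 ± 62.1 FPKM in NEC and 0.496 ± 0.275 in control (SD, n = 3 each), a log2 change of 6.42 (SE 0.36, adjusted p = 0.000585, limma, Benjamini-Hochberg). Lct, which encodes lactase (chromosome 1, 128284756 to 128328318), was at 198 ± 32.1 against 9.11 ± 1.02 FPKM, a log2 change of 4.29 (SE 0.15). Sis, the sucrase-isomaltase gene (chromosome 3, 72888557 to 72967863), was at 31.0 ± 8.84 against 1.51 ± 0.459 FPKM, with a log2 change of 3.65 (SE 0.25). Apoc2, an apolipoprotein that activates lipoprotein lipase, rose by 3.86, Acot12, an acyl-CoA thioesterase, by 3.60, and Leap2, a liver and gut peptide, by 3.55 on the log2 scale. The glutathione S-transferase genes Gstm3 and Gsta1 rose by 5.14 and 3.62, with the reservation that close paralogs share sequence and their split between members is uncertain.

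Among the falls, Afp, the fetal serum protein alpha-fetoprotein (chromosome 5, 90490737 to 90508907), went from 133 ± 15.1 FPKM in control to 4.66 ± 3.06 in NEC, a log2 change of -4.69 (SE 0.34, adjusted p = 0.00124, limma, Benjamini-Hochberg). Gatm, which makes the creatine precursor guanidinoacetate, fell by 3.77 on the log2 scale, and Slc6a14, an amino acid transporter, by 3.71. Anxa8, an annexin, fell by 3.03 and Mdk, the growth factor midkine, by 2.72. Rarres1 went from 40.6 ± 2.22 to 3.80 ± 5.75 FPKM, a log2 change of -3.83 (SE 0.77, adjusted p = 0.0143), and its call was lost without control 1 or control 2. The microRNA gene Mir196a-1, an entry of 102 bases, was at 7.92 ± 0.424 FPKM in control, and at 0, 1.08 and 0.526 in the NEC libraries. Trbd1, a T cell receptor segment spanning 41533201 to 41533212 on chromosome 6, was listed at 0 in all 3 NEC libraries and at 5.33, 5.47 and 5.14 FPKM in the controls. Features as short as Mir196a-1 and Trbd1 have an uncertain FPKM.

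**Figure D1:**
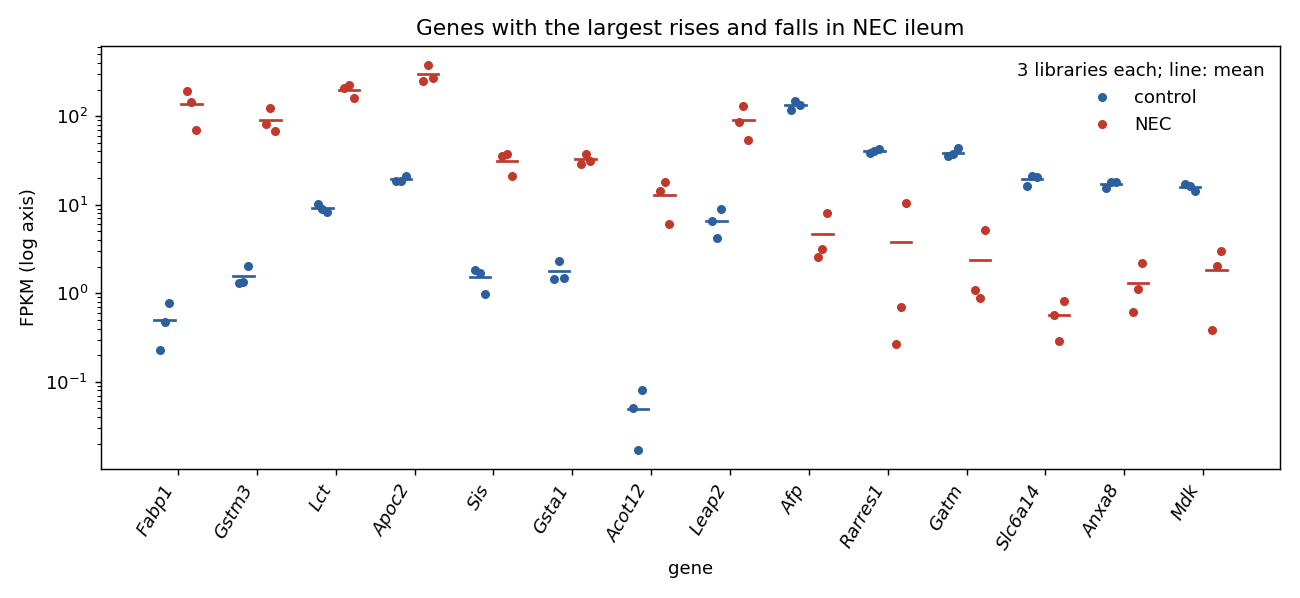
FPKM of each library on a log axis for the genes with the largest rises and falls, with control in blue, NEC in red and a line at each group's mean (n = 3 each). Fabp1 stood between 70.6 and 194 FPKM in NEC and below 1 FPKM in control, and Afp between 117 and 147 in control and at 8.17 or less in NEC. Trbd1 and Mir196a-1 are left out because a log axis cannot show their values of 0.

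Of 15806 genes with a mean of at least 1 FPKM, 6044 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 1215 higher and 4829 lower in NEC. With an absolute log2 change of at least 1 as well, 320 were higher and 939 lower. The groups did not overlap in 59.1% of the tested genes, where chance gives 10%. The excess of falls depended on the scale. The median log2 change of all tested genes was -0.26 on the deposited scale. It was 0.01 after TMM scaling, which called 2655 higher and 2264 lower. It was 0.00 after quantile normalization, which called 2202 higher and 2387 lower. Both methods bring the middle of the changes near 0 by design, so these medians cannot show where the excess came from. Scaling to protein-coding genes outside the 100 most abundant left a median of -0.19, with 1509 higher and 4310 lower. Changes below are on the deposited scale and are to be read against its median of -0.26. That median depends on the level of the genes: among those with a mean of at least 5 FPKM it was -0.15.

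The control libraries resembled one another more than the NEC libraries did. The median within-group SD of log2 values was 0.09 in control and 0.21 in NEC. The first principal component held 70.1% of the variance and placed NEC 1, 2 and 3 at -67.5, -31.9 and -15.6, and the controls at 40.0, 40.9 and 34.2. NEC 1 correlated with NEC 2 and NEC 3 across genes at 0.942 and 0.932, below the 0.972 between NEC 2 and NEC 3. NEC 3 correlated with control 1, 2 and 3 at 0.934, 0.933 and 0.941, each above its value with NEC 1. Leaving out control 2 left 471 genes higher and 917 lower, and leaving out control 1 left 499 and 1049, and without control 3 the counts were 663 and 1979. Without NEC 1, 2 and 3 there were 1566, 795 and 1249 higher and 5371, 2991 and 5378 lower.

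The question in the title concerned autophagy, the delivery of cell contents to lysosomes in double membranes. Single autophagy genes moved in both directions. Vmp1, a membrane protein needed to form autophagosomes (chromosome 11, 86583865 to 86683836), rose from 33.1 ± 1.26 to 69.1 ± 8.27 FPKM (log2 1.03, SE 0.11, adjusted p = 0.00381, limma, Benjamini-Hochberg), and Wipi1, which binds the forming membrane (chromosome 11, 109573331 to 109611967), fell from 9.07 ± 0.265 to 4.62 ± 0.375 FPKM (log2 -0.84, SE 0.09, adjusted p = 0.00404). Both were called with the same direction in each of the 18 alternative settings. Of 36 tested members of the core machinery, 5 were higher, 8 lower and 23 did not pass, with the same counts adjusted over the list alone. The balance depended on the scale: 9 were higher and 3 lower with TMM scaling, and 7 and 2 with quantile normalization. Without NEC 2 they were 1 and 6, and without control 1, 2 and 3 they were 1 and 1, 1 and 1, and 1 and 3.

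The kinase genes Ulk1 and Ulk2, whose products start autophagy, fell by 0.41 and 0.56, and Atg16l2 fell by 0.64 on the log2 scale. The Ulk1 change was -0.10 after TMM scaling and no longer passed, and the Atg16l2 call was lost with quantile normalization. Atg3, Gabarap and Atg9b were higher by 0.37, 0.28 and 1.28. The Gabarap call was lost with quantile normalization and the Atg9b call with TMM scaling, where its adjusted p was 0.056. Becn1 had 6.06 ± 0.161 FPKM in NEC and 6.12 ± 0.532 in control (SD, n = 3 each), and its log2 change of -0.01 became 0.29 with TMM scaling, not passing in either. Map1lc3b had 10.6 ± 5.02 and 15.1 ± 5.86 FPKM, Sqstm1 40.9 ± 14.7 and 31.5 ± 0.604, Atg5 17.0 ± 1.28 and 14.1 ± 0.122, and Atg7 2.54 ± 0.336 and 2.37 ± 0.227 in NEC and control. Of these last 4, none passed (adjusted p = 0.355, 0.307, 0.0676 and 0.664, limma, Benjamini-Hochberg). Atg5 and Atg7 passed as higher with TMM scaling, at 0.58 and 0.32 (adjusted p = 0.00607 and 0.0432), and with quantile normalization, at 0.30 and 0.42 (adjusted p = 0.0272 and 0.022). Without control 1 or control 2 the calls of Ulk1, Ulk2, Atg16l2, Atg3, Gabarap and Atg9b were lost, at adjusted p up to 0.165 for Gabarap.

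Among 38 receptors and regulators of autophagy, 2 were higher, 12 lower and 24 did not pass. Both catalytic subunits of the energy sensor AMPK changed, in opposite directions: Prkaa1 fell from 16.4 ± 0.694 to 9.92 ± 1.27 FPKM and Prkaa2 rose from 19.4 ± 0.622 to 33.1 ± 5.38 FPKM (SD, n = 3 each). The mitophagy genes Pink1 and Bnip3 fell by 0.65 and 0.66, and Dapk1, a death-associated kinase, by 0.93, while the receptor gene Tax1bp1 rose by 0.39. In the broad list of 191 tested autophagy-related genes, 25 were higher, 44 lower and 122 did not pass, and Bak1, Itgb4 and P4hb rose by 0.84, 0.71 and 1.01. The lysosome list had 3 of 38 members higher and 11 lower. Lipa, the lysosomal acid lipase, rose from 14.0 ± 0.221 to 33.7 ± 3.85 FPKM, Atp6v1h rose by 0.46, and Ctss, Ctsh and Galns fell by 0.87, 1.45 and 1.23. With TMM scaling the direction of the broad list turned, to 49 higher and 21 lower, and that of the lysosome list, to 11 and 6, while the calls of the receptors and regulators were 6 and 10, with a median of 0.12 against -0.19 on the deposited scale. Quantile normalization gave 36 and 26, 3 and 11, and 5 and 11 in the same order. Without control 1, 2 and 3 the broad list had 7, 7 and 10 higher and 10, 9 and 19 lower, the lysosome list 1 higher each and 5, 4 and 6 lower, and the receptors and regulators 1 higher each and 6, 5 and 10 lower. Without NEC 2 the broad list had 14 and 28 and the lysosome list 2 and 7. The calls of Tax1bp1 and Atp6v1h were lost without control 1, control 2 or control 3, at adjusted p up to 0.0963 and 0.0624.

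The share of called genes in the autophagy lists did not differ from that of the other tested genes by Fisher's exact test on the deposited scale with the filter. It was 36.1% in the core machinery against 38.2% of other genes (odds ratio 0.913, 95% interval 0.424 to 1.88), and 36.1% in the broad list (odds ratio 0.912, interval 0.668 to 1.24). Receptors and regulators, and likewise lysosome genes, had 36.8% called (odds ratio 0.942, interval 0.450 to 1.90), and the Benjamini-Hochberg adjusted p was 1 in each of the 4 two-sided tests. In limma's camera test against all other genes the broad list was higher (adjusted p = 0.0391, and 0.627 with an estimated correlation), although its median log2 change was -0.09, since the median of all genes lay lower still. That call was lost without NEC 1 (adjusted p = 0.147), without control 1 (0.054), with quantile normalization (0.215), without a filter (0.0985), at a mean of at least 5 FPKM (0.277), with sample weights (0.0828) and with protein-coding genes only (0.0599), and over all settings its adjusted p ranged from 0.00611 to 0.277. For the core machinery, the receptors and regulators, and the lysosome list the camera adjusted p was 0.278, 0.895 and 0.895. The core and lysosome tests pointed up while their medians, -0.11 and -0.18, lay below 0. The fry test asks whether a list moved in a common direction, without comparison with other genes. It called the receptors and regulators lower (fry adjusted p = 0.00904). For the core, broad and lysosome lists it pointed down without passing (0.101, 0.0574 and 0.0991). The median of all genes was itself below 0 on the deposited scale, which favours lower calls in this test. The odds ratios also turned with the setting. With TMM scaling they were 1.11 (core), 1.61 (receptors and regulators), 1.28 (broad) and 1.79 (lysosome), with adjusted p of 0.857, 0.214, 0.198 and 0.198 (Fisher's exact test, Benjamini-Hochberg). Without a filter they were 1.52, 2.21, 1.65 and 1.58 in the same order, and the receptors and regulators and the broad list passed (adjusted p = 0.0454 and 0.00833, Fisher's exact test, Benjamini-Hochberg), against a background that then held many weakly expressed genes.

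**Figure D2:**
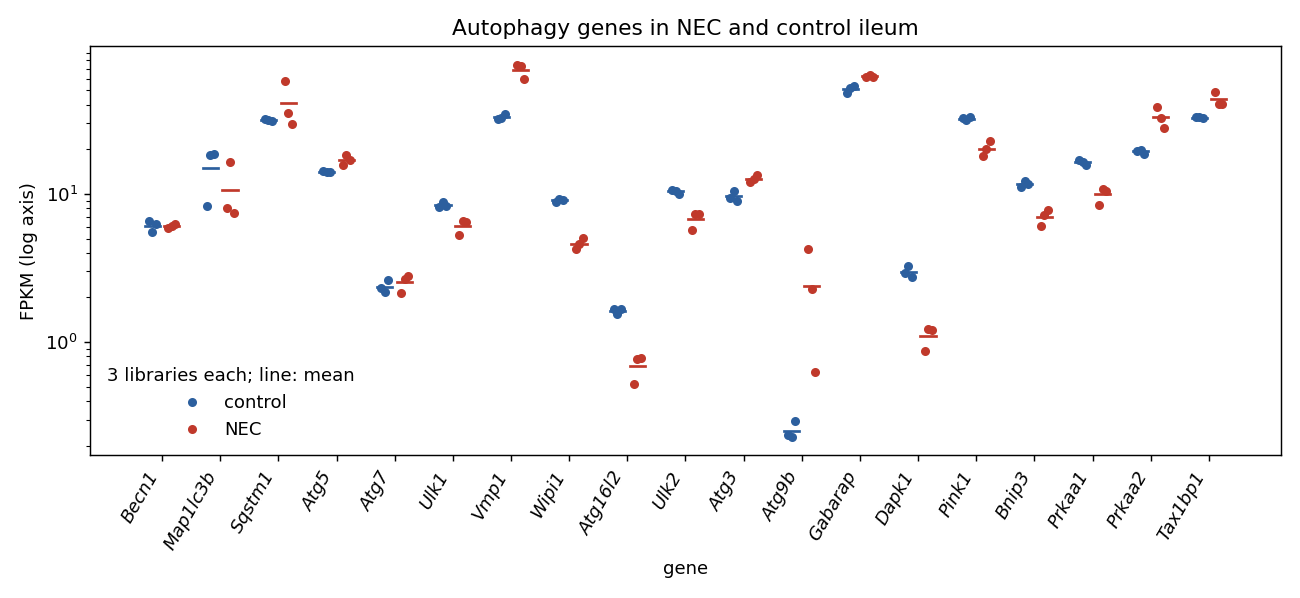
FPKM of each library on a log axis for the autophagy genes named in the text from the core list and the list of receptors and regulators, with control in blue, NEC in red and a line at each group's mean (n = 3 each). Vmp1 stood at 59.6 to 74.7 FPKM in NEC and 32.2 to 34.6 in control, while Becn1 overlapped between the groups.

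Absorptive cell genes rose together. Of 23 tested enterocyte genes, 17 were higher and 1 lower in NEC, with 5 not passing. Fabp2, the intestinal fatty acid-binding protein, went from 96.5 ± 9.12 to 1062 ± 149 FPKM (log2 3.44, SE 0.14), Rbp2, a retinol-binding protein, rose by 2.89 and Mttp, which loads lipid onto lipoproteins, by 2.09. The exception was the amino acid transporter gene Slc7a9 at -0.30, which was 0.05 and not called with TMM scaling, and whose call was also lost without NEC 2 or any 1 control (adjusted p up to 0.151). The list stood above other genes in camera (adjusted p = 1.75e-17 with the preset correlation of 0.01, and 0.229 with an estimated one). With an estimated correlation none of the 31 tested lists was called by camera (4 at an unadjusted p under 0.05), against 13 higher and 3 lower with the preset one, so each estimated value is printed beside its list. The directional fry test, which does not compare a list with other genes, called 4 higher and 8 lower. The median of all tested genes, -0.26, favours lower calls in that test.

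Of 3 tested genes of the adult-type enterocyte, Sis and Krt20 rose and Maf did not pass. Among 14 genes of the suckling-type ileal enterocyte 2 were higher and 3 lower (adjusted p = 0.58): Lct and the urea cycle gene Ass1 rose, by 4.29 and 0.36, and Lrp2, an endocytic receptor, and the oxidase gene Nox4 fell by 1.85 and 0.75. The Nox4 call was lost with TMM scaling, where the list had 3 higher and 1 lower, and without NEC 3 it had 2 higher and 6 lower. Of 5 tested genes of the upper small intestine, 3 were higher, Fabp1 among them, and 1 lower (camera adjusted p = 0.000643, and 0.355 with an estimated correlation). Apoa4, an apolipoprotein of fat absorption, stood at 9610 ± 1244 FPKM against 1904 ± 254, Gata4, a transcription factor of the upper bowel, at 6.32 ± 2.27 against 0.111 ± 0.0650, and Cybrd1 was lower by -0.44, a call lost with TMM scaling. Bile acid handling genes had 3 of 8 higher and 1 lower (adjusted p = 0.0141, and 0.395 estimated): the transporter genes Slc51a, Slc51b and Abcc2 rose by 0.94, 1.98 and 1.20, and the hormone gene Fgf15 fell from 5.80 ± 0.221 to 0.627 ± 0.651 FPKM. The bile acid list did not pass with TMM scaling, with quantile normalization or without NEC 3 (adjusted p = 0.0632, 0.0806 and 0.106). Leaving out control 1 or control 2 ended the calls of Krt20, Ass1, Nox4 and Cybrd1, at adjusted p up to 0.136 for Cybrd1, and left 1 higher and 1 lower in the suckling-type list.

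In fatty acid oxidation, 12 of 17 genes were higher and none lower (adjusted p = 2.49e-12, and 0.229 estimated). Pdk4, which turns cells from glucose to fat use, rose by 2.50 on the log2 scale (SE 0.17, adjusted p = 0.00108), and the lipid droplet gene Plin2 and Acadl rose by 1.16 and 0.88. In cholesterol synthesis 11 of 18 genes were higher and none lower, or 13 adjusted over the list alone (adjusted p = 8.15e-12, and 0.333 estimated). Sqle, Fdps and Sc5d rose by 1.24, 0.87 and 0.76. Of 9 glucocorticoid-responsive genes 5 were higher and none lower (adjusted p = 6.51e-06, and 0.389 estimated). The metallothionein genes Mt1 and Mt2 rose by 2.07 and 2.20, Hif3a by 0.48 and Fkbp5 by 2.01, the last with 17.4 FPKM in NEC 1 and 3.37 and 2.80 in NEC 2 and 3. The Hif3a and Fkbp5 calls were lost without any 1 of the controls, at adjusted p up to 0.0891 and 0.0986, and 2 genes of their list then passed, against 3 without NEC 2. Without control 1 and control 2, 7 and 7 genes of fatty acid oxidation and 8 and 6 of cholesterol synthesis passed as higher.

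Most stem cell genes were lower. Lgr5, a marker of intestinal stem cells (chromosome 10, 115450311 to 115587780), fell from 6.13 ± 0.0246 to 0.583 ± 0.391 FPKM (log2 -2.20, SE 0.19, adjusted p = 0.002, limma, Benjamini-Hochberg). Of 12 stem cell genes 9 were lower and none higher (camera adjusted p = 0.0168, and 0.558 estimated), Msi1, Tnfrsf19 and Lrig1 by -0.81, -1.43 and -0.87. The list did not pass at a mean of at least 5 FPKM, with 4 genes tested (adjusted p = 0.164). With TMM scaling 7 were lower, and without NEC 2 and control 1, 2 and 3 there were 5, 2, 2 and 4. Proliferation genes had 9 of 22 lower and none higher (adjusted p = 0.0527). With TMM scaling the list's adjusted p was 0.00932 while 3 genes were lower, and 4 were lower with quantile normalization and 4 without NEC 2, against 0 without any 1 of the controls. Cdk1, Aurkb, Ccnb2 and Mcm3 fell by 0.92, 0.78, 1.39 and 0.73, and the Mcm3 call was lost with TMM scaling. The proliferation list passed without NEC 1, NEC 2, NEC 3 or control 2 (adjusted p = 0.0109, 0.0357, 0.0279 and 0.0431). The calls of Tnfrsf19, Lrig1, Cdk1, Aurkb, Ccnb2 and Mcm3 were lost without control 1 or control 2, at adjusted p up to 0.0931 for Mcm3.

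The secretory lists did not differ from other genes on the deposited scale. Muc2, the main mucin of goblet cells, had 73.8 ± 15.4 FPKM in NEC and 75.7 ± 14.9 in control (adjusted p = 0.894). Of 9 goblet cell genes 1 was higher and 4 lower (adjusted p = 0.801). Atoh1, a transcription factor of secretory cells, fell by 1.05 and Zg16 rose by 1.41, while the calls of Spdef at -0.50 and Spink4 at -2.10 were lost with TMM scaling, which left 1 higher and 1 lower. Paneth cell genes had 3 of 7 lower and none higher (adjusted p = 0.166, and 0.0445 with TMM scaling): Sox9, Ang4 and Cd24a fell by 1.04, 1.75 and 0.77, and Defa17 had 5.66, 15.9 and 18.1 FPKM in NEC against 110, 71.3 and 12.1 in control. Enteroendocrine genes had 1 of 9 higher and 3 lower (adjusted p = 0.895): the hormone gene Gip rose from 0.0637 ± 0.110 to 3.35 ± 1.43 FPKM, Pyy fell by 1.24, and the calls of Sst at -0.81 and Sct at -0.88 were lost with TMM scaling, which also left 1 higher and 1 lower. Without NEC 3 that list had 1 higher and 5 lower, and without NEC 1 the goblet list 0 and 2. Leaving out control 3 took the Paneth cell list to an adjusted p of 0.00845. The calls of Atoh1, Zg16, Spdef, Spink4, Cd24a, Pyy, Sst and Sct were lost without control 1 or control 2, at adjusted p up to 0.123 for Spink4.

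Inflammatory genes gave no common direction. Tlr4, the lipopolysaccharide receptor, lay below the filter, at 0.638, 0.130 and 0.127 FPKM in NEC and 1.38, 0.875 and 1.83 in control. Of 15 tested genes of the TLR4 and NF-kB response 2 were higher and 2 lower (adjusted p = 0.0391, and 0.632 estimated): Il1a and Tnfaip3 rose by 1.35 and 0.56, and Ptgs2 and Ccl20 fell by 1.02 and 0.75, the Ccl20 call being lost with quantile normalization (adjusted p = 0.105). Without NEC 1 the counts were 0 and 4 of 14 and without NEC 2 0 and 2, as Il1a then lay below the filter and Tnfaip3 did not pass (adjusted p = 0.07 and 0.106). Without NEC 3 they were 4 and 2. Adjusted over the list alone, 1 was higher and 2 lower, and the list's adjusted p was 0.755 without NEC 1, 0.057 without control 1, 0.229 with TMM scaling, 0.142 with quantile normalization, 0.205 at a mean of at least 5 FPKM, 0.202 with sample weights, 0.0614 scaled outside the 100 most abundant genes and 0.0599 with protein-coding genes only. None of 26 interferon response genes passed (limma, Benjamini-Hochberg), 0 of them at an unadjusted p under 0.05, although the list stood higher in camera (adjusted p = 8.69e-05, and 0.672 estimated). NEC 1 carried it: Rsad2 was at 138.6 FPKM there and at 2.11 and 1.78 in NEC 2 and 3, Stat2 at 44.0 against 10.7 and 13.4, and without NEC 1 the difference of the list's mean from other genes was -0.13 (adjusted p = 0.491) and 6 of 20 tested members were called lower. The interferon list did not pass with TMM scaling or quantile normalization (adjusted p = 0.0686 and 0.0535), at a mean of at least 5 FPKM (0.0781) or with sample weights (0.202). The epithelial antimicrobial list had 1 of 6 genes lower and none higher (adjusted p = 0.118), with Reg3g at 109, 1.60 and 13.7 FPKM in the NEC libraries and 2.10 ± 0.340 in control, and Pglyrp1 at -0.55, a call lost with TMM scaling. That list passed as higher without NEC 2, control 2 or control 3 (adjusted p = 0.00108, 0.0195 and 0.0266). The Il1a, Tnfaip3 and Pglyrp1 calls were lost without control 1 or control 2, at adjusted p up to 0.121 for Tnfaip3 over all libraries left out.

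Cell death and inflammasome genes had 5 of 20 higher and 3 lower (adjusted p = 0.00596, and 0.389 estimated). Gsdmd, a pore-forming protein of pyroptosis, rose by 1.03 on the log2 scale (SE 0.18, adjusted p = 0.0103), and Il18, Bak1 and Casp8 rose by 1.44, 0.84 and 0.74. Pycard and Nlrp6 were at -0.59 and -0.73, calls lost with TMM scaling, where the list had 7 higher and none lower but did not pass (adjusted p = 0.056, 0.0596 with quantile normalization and 0.164 at a mean of at least 5 FPKM), against 3 and 0 without any 1 of the controls. Of 25 hypoxia genes 6 were higher and 8 lower (adjusted p = 0.0484, and 0.395 estimated): the glycolysis genes Pfkfb4 and Ldha rose by 1.24 and 0.70, and Slc2a1 and Kdm3a fell by 0.93 and 0.64, and Ankrd37 went from 4.22 ± 0.0582 to 1.16 ± 0.497 FPKM. The mean of the hypoxia list was -0.03, against the direction of its test, and the counts were 11 higher and 7 lower with TMM scaling, 7 and 7 with quantile normalization (list adjusted p = 0.231 and 0.51), and 3 and 4, and 2 and 4, without control 1 and control 2. Without NEC 1 the adjusted p was 0.0561 for the cell death list and 0.0699 for the hypoxia list, and the latter was 0.0716 and 0.0619 without control 1 and control 3. The hypoxia list also did not pass at a mean of at least 5 FPKM (0.0781), with sample weights (0.0828), scaled outside the 100 most abundant genes (0.0614), with protein-coding genes only (0.064) or without X and Y (0.0538). The unfolded protein response had 2 of 22 higher and none lower, Dnajb9 by 0.56 and Asns by 0.79, with 1 higher adjusted over the list alone (adjusted p = 0.00092, and 0.333 estimated). The count depended on the setting, with 9 higher under TMM scaling, 5 under quantile normalization, where the list did not pass (adjusted p = 0.067, and 0.164 at a mean of at least 5 FPKM), 4 and 2 lower without NEC 1, 1 without NEC 2, 7 and 2 lower without NEC 3, and 0, 0 and 1 without control 1, 2 and 3. Of 17 tight junction and adhesion genes 3 were higher and 1 lower (adjusted p = 0.0749), Cgn and Marveld3 by 0.37 and 0.29, and Cldn8, a claudin, by -1.64. The test of this last list passed without control 3 (adjusted p = 0.0473), where 1 was higher and 1 lower, and with TMM scaling 5 were higher and 1 lower. Without NEC 3 it had 3 and 3, and without control 1 and control 2 none higher and 1 and 0 lower. Without control 2 the calls of Casp8, Pycard, Nlrp6, Dnajb9, Asns, Cgn, Marveld3 and Cldn8 were lost, at adjusted p from 0.0513 for Cldn8 to 0.143 for Marveld3.

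Fibroblast genes were mostly lower, and other cell types of the bowel wall gave mixed counts. Of 11 fibroblast genes 10 were lower and none higher (adjusted p = 0.0141, and 0.632 estimated), with Col6a1 falling from 99.2 ± 7.98 to 31.9 ± 11.3 FPKM, Col6a2 by 1.54 and Col1a2 by 1.63. Pdgfrb, at -0.52, lost its call with TMM scaling, which left 6 lower, and without NEC 2 and control 1, 2 and 3 there were 6, 2, 2 and 3. Enteric neuron and glia genes had 5 of 7 lower and none higher (adjusted p = 0.109), Uchl1, Elavl4 and Nos1 by -1.03, -0.63 and -0.65. The Elavl4 and Nos1 calls were lost with quantile normalization, which left 3 lower, and without NEC 2 and control 1, 2 and 3 there were 3, 1, 1 and 3. Of 10 endothelial genes 4 were lower and 1 higher (adjusted p = 0.918): Cldn5 and Pecam1 fell by 1.19 and 0.80, Cdh5 was at -0.48, a call lost with TMM scaling, and Plvap rose by 0.40. The balance turned to 3 higher and 2 lower with TMM scaling and was 3 and 3 with quantile normalization, 3 and 5 without NEC 1, and 0 and 1, and 0 and 2, without control 2 and control 3. None of 11 smooth muscle genes passed (limma, Benjamini-Hochberg, 3 at an unadjusted p under 0.05, list adjusted p = 0.366), with Acta2 at 38.4 FPKM in NEC 1 and 197 and 219 in NEC 2 and 3, against 323 ± 35.1 in control. Without NEC 1, 7 smooth muscle genes were called lower, and 3 without NEC 3. Without control 2 the calls of Col1a2, Pdgfrb, Elavl4, Nos1, Pecam1, Cdh5 and Plvap were lost, with adjusted p of 0.0764 for Col1a2 and 0.058 for Pecam1.

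Of 5 erythroid genes 4 were lower and none higher (adjusted p = 0.0141, and 0.592 estimated), with the globin gene Hbb-bt falling from 291 ± 30.4 to 63.2 ± 2.52 FPKM and Alas2, Hbb-bs and Hba-a1 by 1.61, 1.39 and 1.44, globin copies that share sequence. Macrophage genes had 3 of 9 lower and none higher, and 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.911). Adgre1 fell by 0.87, and C1qa and C1qb, at -0.48 and -0.47, lost their calls with TMM scaling. That list turned to 3 higher and 1 lower with TMM scaling and to 1 and 0 with quantile normalization, where the Adgre1 call was lost too, and had 0 and 5 without NEC 3, 0 and 2 without NEC 2, and no call without control 1 or control 2. None of 6 neutrophil genes passed (limma, Benjamini-Hochberg, 2 at an unadjusted p under 0.05, list adjusted p = 0.0484, and 0.627 estimated), and S100a8 was at 1.69 FPKM in control 1 and between 23.1 and 27.4 in the other 5 libraries. Of 3 B and plasma cell genes Ighm fell by 1.19, with 3 lower adjusted over the list alone, and no T cell gene reached the filter. Immediate early and heat shock genes, which mark handling of tissue, had 4 of 9 lower and none higher, or 4 and 1 adjusted over the list alone (adjusted p = 0.86). Hspa1a fell by 0.69, and Egr1, Dusp1 and Hspa1b, at -0.65, -0.46 and -0.75, lost their calls with TMM scaling, and the Hspa1a call was lost with quantile normalization, which left no call in that list. Among neighbouring tissues, the pancreatic gene Ctrb1 rose by 2.22, the large intestine gene Slc26a3 had a log2 change of 0.50 and did not pass, and of 2 fat genes Cidec rose by 1.86 and Plin4 did not pass. Slc26a3 passed as higher with TMM scaling, at 0.81 (adjusted p = 0.04). The erythroid list had an adjusted p of 0.0511 without NEC 3, 0.0591 at a mean of at least 5 FPKM and 0.0642 with sample weights, and the neutrophil list 0.0799, 0.0753 and 0.467 without NEC 1, NEC 3 and control 1, 0.201 with TMM scaling and 0.17 with quantile normalization. It was 0.164 for the neutrophil list at a mean of at least 5 FPKM, 0.0917 with sample weights, 0.0665 scaled outside the 100 most abundant genes, 0.064 with protein-coding genes only and 0.0518 without X and Y. The calls of Adgre1, C1qa, C1qb, Ighm, Hspa1a, Egr1, Dusp1, Hspa1b and Ctrb1 were lost without control 2, Ctrb1 at an adjusted p of 0.0725. Of the neutrophil genes 1 was called higher with TMM scaling, with quantile normalization and without NEC 1, and 1 lower without NEC 3.

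**Figure D3:**
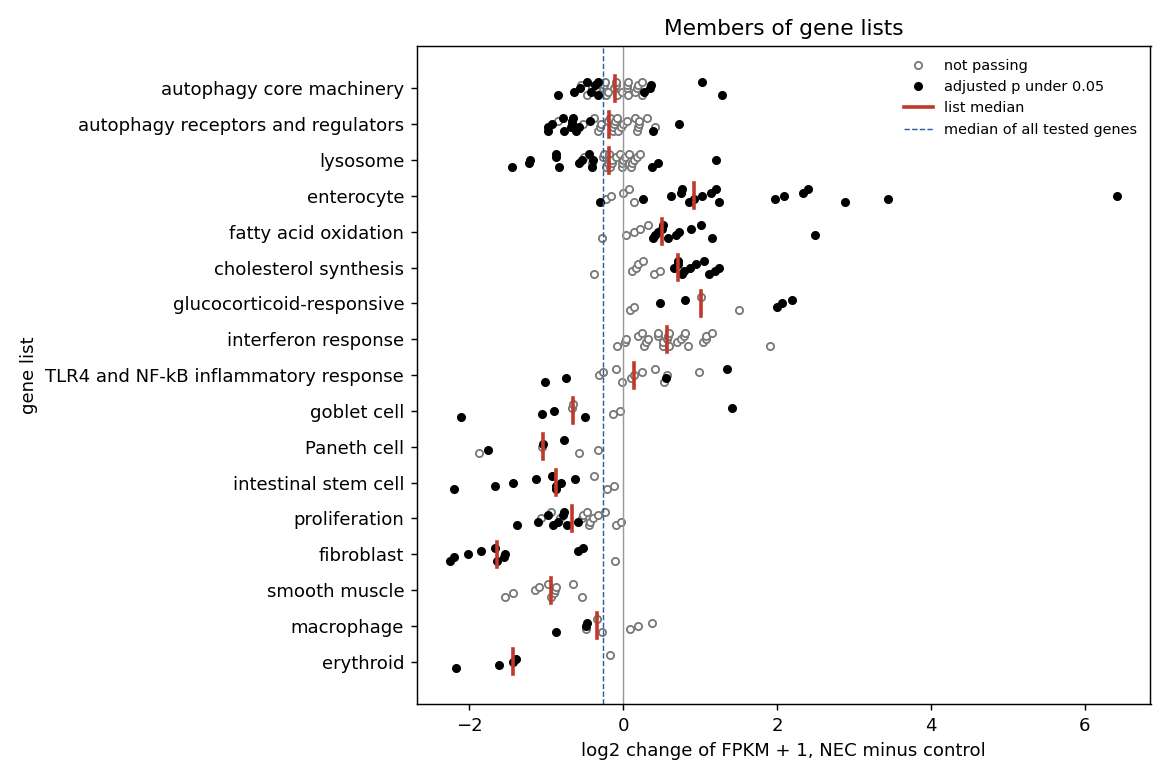
Log2 change of FPKM + 1, NEC minus control, of each tested member of 17 gene lists, filled where the adjusted p was under 0.05, with the list median in red and the median of all tested genes, -0.26, as a dashed line. Enterocyte, fatty acid oxidation and cholesterol synthesis genes lay mostly to the right and stem cell, fibroblast and erythroid genes to the left.

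The named calls differed in how far they held. Of 135 named genes that passed, 71 were called with the same direction in each alternative setting that gave a value, among them Fabp1, Lct, Afp, Vmp1, Wipi1, Fabp2, Pdk4, Gata4 and Lgr5. TMM scaling kept 113 of the calls and quantile normalization 111. Leaving out control 2 ended 63 of them, control 1 59, control 3 40, and NEC 1, 2 and 3 ended 6, 31 and 10.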

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

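The values here are those that differed from the reported ones, with list values given as the mean log2 change against other genes. An estimated correlation in camera gave 0 lists higher and 0 lists lower. The fry test gave 4 lists higher and 8 lists lower. Calls with a log2 change of at least 1 turned the odds ratio of calls to 1.36 (lysosome). A pseudocount of 0.1 gave 1941 lower by log2 1 or more. It turned the odds ratio of calls to 1.08 (lysosome). This setting also turned the sign of the list value to 0.034 (receptors), 0.17 (enteroendocrine cell) and 0.033 (macrophage). A pseudocount of 0.01 gave 1987 lower by log2 1 or more. It turned the odds ratio of calls to 1.11 (lysosome). This setting also turned the sign of the list value to 0.0469 (receptors), 0.44 (enteroendocrine cell), 0.0478 (macrophage) and 0.00787 (endothelium). Testing without a filter gave 6 lists lower. It turned the odds ratio of calls to 1.52 (autophagy core), 2.21 (receptors), 1.65 (broad autophagy) and 1.58 (lysosome). This setting also turned the sign of the list value to -0.0633 (lysosome) and -0.0229 (tight junction). Further, it ended the list call at 0.0914 (broad autophagy). In addition it added a list call at 0.71 (antimicrobial), -0.48 (proliferation) and -0.43 (neuron and glia). A minimum mean of 5 FPKM gave 1746 genes lower, 419 lower by log2 1 or more, 5 lists higher and 1 list lower. It turned the sign of the list value to -0.0886 (lysosome) and -0.0602 (tight junction). This setting also ended the list call at 0.14 (broad autophagy), -0.87 (stem cell), 0.43 (TLR4), 0.78 (interferon), 0.34 (cell death), 0.32 (hypoxia), 0.25 (unfolded protein response), 0.79 (neutrophil) and -1.15 (erythroid). TMM scaling gave 2655 genes higher, 2264 genes lower, 606 higher by log2 1 or more, 370 lower by log2 1 or more, 7 lists higher and 5 lists lower. It turned the odds ratio of calls to 1.11 (autophagy core), 1.61 (receptors), 1.28 (broad autophagy) and 1.79 (lysosome). This setting also turned the sign of the list value to 0.0198 (receptors). Further, it ended the list call at 0.48 (bile acid), 0.41 (TLR4), 0.84 (interferon), 0.46 (cell death), 0.24 (hypoxia) and 0.72 (neutrophil). In addition it added a list call at -0.79 (Paneth cell) and -0.42 (proliferation). Last, it turned the gene change to 0.29 (Becn1), 0.31 (Muc2), 0.15 (Maf) and 0.0473 (Slc7a9). Quantile normalization gave 2202 genes higher, 2387 genes lower, 425 lower by log2 1 or more, 5 lists higher and 7 lists lower. It turned the odds ratio of calls to 1.78 (receptors), 1.18 (broad autophagy) and 1.43 (lysosome). This setting also turned the sign of the list value to -0.17 (lysosome) and -0.15 (tight junction). Further, it ended the list call at 0.0944 (broad autophagy), 0.43 (bile acid), 0.42 (TLR4), 0.81 (interferon), 0.39 (cell death), 0.15 (hypoxia), 0.36 (unfolded protein response) and 0.68 (neutrophil). In addition it added a list call at -0.86 (Paneth cell), -0.38 (proliferation), -0.91 (smooth muscle) and -0.53 (neuron and glia). Last, it turned the gene change to 0.22 (Becn1) and 0.15 (Plin4). The replicate block, under which 4086 genes passed, turned the odds ratio of calls to 1.17 (receptors). It added a list call at -0.41 (proliferation). Weighting the samples gave 8 lists higher. It turned the odds ratio of calls to 1.34 (autophagy core), 1.06 (broad autophagy) and 1.32 (lysosome). This setting also turned the sign of the list value to -0.00988 (tight junction) and 0.00435 (endothelium). Further, it ended the list call at 0.14 (broad autophagy), 0.23 (TLR4), 0.0807 (interferon), 0.17 (hypoxia), 0.77 (neutrophil) and -1.13 (erythroid). In addition it added a list call at -0.26 (proliferation). Last, it turned the gene change to 0.00197 (Becn1) and 0.0197 (Muc2). Scaling outside the 100 most abundant genes, chosen after seeing the data, turned the odds ratio of calls to 1.09 (autophagy core) and 1.12 (lysosome). It turned the sign of the list value to 0.000417 (receptors). This setting also ended the list call at 0.41 (TLR4), 0.22 (hypoxia) and 0.72 (neutrophil). Further, it added a list call at -0.41 (proliferation) and 0.0627 (tight junction). In addition it turned the gene change to 0.0675 (Becn1) and 0.0493 (Muc2). Protein-coding genes alone, also chosen after seeing the data, turned the sign of the list value to -0.00492 (lysosome). It ended the list call at 0.16 (broad autophagy), 0.40 (TLR4), 0.20 (hypoxia) and 0.70 (neutrophil). Leaving out X and Y, also chosen after seeing the data, turned the odds ratio of calls to 1.09 (lysosome). It turned the sign of the list value to -0.00321 (lysosome). This setting also ended the list call at 0.21 (hypoxia) and 0.71 (neutrophil). Leaving out each library in turn, where the other 2 libraries of its group carry the spread, gave counts of 441 to 1431 (lower by log2 1 or more), 7 to 15 (lists higher), 471 to 1566 (genes higher) and 917 to 5378 (genes lower). Over these fits the odds ratios ran from 0.88 to 1.01 (broad autophagy), 1.0004 to 1.70 (lysosome) and 0.89 to 2.05 (receptors). List values in the same fits ran from 0.11 to 0.22 (broad autophagy), -0.53 to -0.20 (proliferation), 0.0662 to 0.59 (TLR4), -0.13 to 1.34 (interferon), 0.26 to 0.53 (cell death), 0.15 to 0.27 (hypoxia), 0.19 to 0.99 (neutrophil) and -0.0749 to 0.0234 (endothelium). For the remaining lists they ran from -0.0436 to 0.24 (immediate early genes), -0.0394 to 0.0258 (receptors), 0.49 to 1.55 (antimicrobial), -0.0201 to 0.0314 (lysosome), 0.31 to 0.64 (bile acid), -1.31 to -0.99988 (erythroid), -0.0728 to 0.000663 (macrophage), -1.20 to -0.57 (Paneth cell) and 0.00926 to 0.11 (tight junction). Gene changes ran from -0.071 to 0.0333 (Becn1), -0.20 to 0.13 (Muc2), -0.43 to 0.0565 (Plin4), -0.0178 to 1.42 (S100a9) and -0.0527 to 1.61 (S100a8). No gene called in NEC against control changed direction in a setting that also called it (limma, Benjamini-Hochberg). The replicate numbers did not pair the libraries, so the replicate block is given only as an alternative. A count test on recovered fragments was planned and not run, since whole fragments came out for single-transcript genes only.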

Other observations

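The tests of the regional and sex-linked patterns and of non-coding RNA below, and the gene families in the next paragraph, were chosen only after the results were seen. The tests of other splits, of the most abundant genes and of transcript length were written before their results were seen.

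Some antioxidant and conjugation families, picked after their values were seen and not tested for enrichment, had many members higher in NEC, where 1215 of 15806 tested genes were higher and 4829 lower. Of 18 tested glutathione S-transferase genes 13 were higher and none lower, and 14 were higher with TMM scaling. Of 8 tested genes linked to the transcription factor NRF2, 7 were higher on the deposited scale and 8 with TMM scaling. Nqo1, a quinone reductase, went from 6.83 ± 0.858 to 42.0 ± 5.08 FPKM (SD, n = 3 each), Gclc, which starts glutathione synthesis, from 17.4 ± 0.296 to 97.6 ± 39.7, Srxn1 from 55.1 ± 2.03 to 156 ± 22.7 and Me1 from 5.01 ± 1.11 to 45.6 ± 14.0. UDP-glucuronosyltransferase genes had 8 of 14 higher, and 11 with TMM scaling. Cyp2c genes showed no such pattern, with 1 of 4 higher in both and a median of -0.12.

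Other families picked in the same way had many members lower. Of 7 tested imprinted growth genes 6 were lower on the deposited scale and 4 with TMM scaling, with H19 going from 17.4 ± 6.92 to 2.30 ± 0.812 FPKM and Mest from 7.42 ± 0.584 to 1.56 ± 0.951. Of 64 replication-dependent histone genes 53 were lower and 1 higher, and 35 and 1 with TMM scaling. Their transcripts mostly lack a poly(A) tail and their copies share sequence, so these values also depend on library preparation. Adamdec1, a metalloprotease gene, went from 482 ± 50.3 to 114 ± 52.5 FPKM, and the interleukin receptor gene Il18r1 from 9.88 ± 0.508 to 0.940 ± 0.486. Acta1, skeletal muscle actin, went from 0.577 ± 0.241 to 17.4 ± 9.56 FPKM.

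NEC and control also differed in genes that mark position along the gut. Gata4, Fabp1 and Apoa4 were higher, and 13 of 15 tested Hox genes were lower and none higher, or 9 with TMM scaling, while Cybrd1, another upper small intestine gene, was lower, a call lost with TMM scaling. A larger share of epithelium is a candidate explanation, and it stays open for the upper small intestine list as a whole. With TMM scaling, 8 pan-epithelial genes such as Epcam and Cdh1 changed by a mean of 0.33, from -1.06 for Krt19 to 1.10 for Vil1. The 95% interval of that mean, up to 0.87, measures the spread among these 8 genes and not between libraries. Its upper end lies below the list's median of 2.69 on that scale and above the list's smallest called rise, 0.38 for Slc40a1. For the Hox genes a change in tissue share was not tested, and 10 of 11 fibroblast genes were lower too. Tissue taken nearer the jejunum in NEC could also give the differences in these position genes. It cannot be told apart from an effect of NEC here, since a difference in site would go with the group. Hox groups 6 to 9 fell by 0.49 more than groups 1 to 5 with TMM scaling (difference of medians -0.49, exact permutation p = 0.204 over genes). The difference lies in the direction this explanation predicts. The permutation treats 15 genes of related families as independent, so it cannot decide the question. The bile acid transporter genes Slc51a and Slc51b, which belong to the ileum, were higher by 0.94 and 1.98, and Slc26a3, a large intestine gene, passed as higher with TMM scaling, values that go against this explanation without excluding it.

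The libraries also differed in sex-linked genes. Xist, expressed from the inactive X, was at 130 and 139 FPKM in NEC 2 and 3 and at 0.221 or less in the other 4, while the Y-linked gene Ddx3y was at 6.78 FPKM in NEC 1, between 7.55 and 9.89 in the controls, and at 0.0119 or less in NEC 2 and 3. A sex difference as the source of the calls was tested through NEC 1, which shares the Y-linked genes with the controls. Of 6683 autosomal genes called from NEC 2 and 3 against the controls, 95.3% lay on the called side in NEC 1. The share was 93.7% of 5431 when the controls were split between both comparisons. These shares go against sex as the main source, with a limit. The deposited scale itself favours agreement: without NEC 1, 1566 genes were called higher and 5371 lower. NEC 1 had the lowest TMM factor, 0.779 against 1.11 to 1.14 in the controls. The share to expect from this scale alone was not measured. Effects of sex on single genes, litter and handling stay untested.

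Most tested genes were lower in NEC on the deposited scale (median log2 change -0.26), and abundant non-coding RNA taking up the FPKM total would leave a median near 0 after scaling to the protein-coding total, and the median was -0.31. Abundant protein-coding genes held more of that total in NEC. The 100 most abundant took 34.1%, 31.2% and 31.3% in NEC 1, 2 and 3 against 23.6%, 24.3% and 25.2% in control 1, 2 and 3. Scaling to the other protein-coding genes left a median of -0.19, so these 100 genes may account for part of the shift. Only this cut of 100 was used, so the value cannot show how much a wider set of abundant genes would account for. Among genes with a mean of at least 5 FPKM the median on the deposited scale was -0.15. Loss of long transcripts would spare the shortest, and the shortest protein-coding genes by rank had a median of -0.21, against -0.29 for the longest. Mitochondrially encoded genes held 10.6%, 7.98% and 8.89% of protein-coding FPKM in NEC 1, 2 and 3 and 5.90%, 6.66% and 6.78% in control 1, 2 and 3, so tissue or RNA quality may also differ with the group. What remains may be a change in how expression is spread over genes or a technical difference between the groups, which the design does not separate.

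The real grouping called 6044 genes and the highest of the other splits of the 6 libraries 2, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. The short non-coding gene Gm22133, picked after its values were seen, was at 1750 ± 221 FPKM in control and 0.513 ± 0.0260 in NEC, and Gm47299 was at 44901, 0.689 and 22210 FPKM in the NEC libraries.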
